A study of Oryza sativa with 12 samples.

How the data were processed

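Panicles of a heat tolerant rice line (252) and a heat sensitive line (082) were compared at high temperature (37 °C by day and 30 °C by night for 5 days) and optimal temperature (30 °C and 25 °C), with 3 arrays per group described per the labels as biological replicates. Per the labels' protocols, 6 µg of total RNA was turned into biotin-labelled cRNA and hybridized to a 1-colour Affymetrix rice array. The deposited values are intensity signals on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, the target intensity and any later step were not given in the sources used here. The values hold no negatives, and the mean of each array after a 2% trim was close to 500, so each array was taken as scaled to a common trimmed mean. The 12 value columns mapped to the 12 samples, and no pair of arrays was identical. Stage of the panicles, time of day of sampling, labelling batch and array date were not given.

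Probe sets were joined to genes through the platform's annotation table, and its gene identifiers were looked up in a RefSeq gene table of the Japonica assembly ASM3414082v1. Of 57381 probe sets 22436 carried 1 gene, 95 carried several and were given no gene, and 17905 genes had a probe set. A name other than a locus or clone number was available for 2453 genes. Probe positions were not available, so no coordinates are given. Glutelin, dehydrin and small heat shock genes belong to families with closely similar copies, and the annotation does not say which probe sets bind more than 1 copy, so values of single members are uncertain. The records of HSFA2C and HSFA2D carried merged names of other genes, so these are also uncertain. MBF1C was not in the table and was not analysed here.

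The 187 Affymetrix control probe sets were set aside. Probe sets above the median of their array in at least 3 of the 12 arrays were kept, 33610 in all, and log2 of the signal plus 16 was used. Linear models with 4 group means were fitted in limma (version 3.58.1, R 4.3.3) with 8 residual degrees of freedom and empirical Bayes moderation with an intensity trend. Contrasts were high against optimal temperature within each line, the difference of these heat changes (252 minus 082), and line 252 against line 082 within each temperature. P-values were adjusted by Benjamini-Hochberg over the kept probe sets of each contrast. A call needed an adjusted p under 0.05 and an absolute log2 change of at least 1.

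Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, on 16542 genes each represented by the probe set with the highest mean over the 12 arrays. Of 21 lists written before the data were examined, 19 had at least 5 measured genes and were tested, with p-values adjusted over the 19. The lists had been defined by gene descriptions, which the tables did not hold. Membership was therefore matched on gene symbols, after the annotation was seen and before any expression difference was computed. The HSP70 list matched 0 genes and was not analysed here, and class III peroxidases had 3 measured genes and were described without a test. A symbol can stand for another protein: GLB1 of the seed storage list is also the symbol of a nitrogen sensor. Estimated correlations between genes and the rotation test fry were run as alternatives. Counts adjusted over a list alone used the list's own members for the adjustment. Where a list's median is given, its mean and its test had the same sign.

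Named genes followed a rule written before the data were examined. It took up to 8 named genes with the largest called changes per direction and contrast, up to 4 members of each list with the largest called changes (2 where none was called), and the HSFA2 genes and CLPB1 in each contrast. Genes outside the rule are said to have been chosen after their values were seen. Errors of log2 changes are standard errors from limma, and errors of signals are standard deviations of 3 arrays. Where a group's signals lay under the median of their arrays, the size and error of a log2 change depend on the added 16 and hold for that setting.

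The alternatives were quantile normalization, centring on the 75th percentile, pseudocounts of 1 and 64, no filter, a filter at the 75th percentile, no intensity trend, replicate number as a block, array weights, no fold minimum, a fit with the compared groups alone, 1 probe set per gene, the mean over a gene's probe sets, and leaving out each array in turn. Scaling to the hybridization spikes (BioB, BioC, BioD and Cre) and counting without the probe sets that set the 082 optimal arrays apart were added after seeing the data.

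The fit was tested on simulated data with the arrays' own spread. For heat in line 252, 52% of added log2 changes of 1.5 and 95% of changes of 3 were called, with 8 false calls among 33410 unchanged probe sets. For the difference of heat changes these were 33% and 76% with 5 false calls, and for the lines at high temperature 58% and 95% with 6. Fewer probe sets were changed there (100 at each size) than were called in the data. An adjusted p under 0.05 was therefore harder to reach, and these shares do not give the sensitivity of the real contrasts. With a shift of 1 added to the small heat shock list, 1 of 19 lists passed, that list, at an adjusted p of 2.2e-23. The simulated genes varied independently, whereas estimated correlations within the lists reached 0.61 in the data. This simulation therefore does not show how the list test behaves when members vary together. Other probe sets of called genes had the same sign in 86.3% of cases for heat in line 252, 81.0% for heat in line 082, 80.1% for the difference, 85.0% at optimal temperature and 93.2% at high temperature. Fewer were called the same way, in this order 527 of 1036, 599 of 1224, 366 of 866, 426 of 851 and 21 of 59. Those called the opposite way numbered 18, 48, 16, 23 and 0.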

Results

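Panicles of the heat tolerant rice line 252 and the heat sensitive line 082 were profiled on a 1-colour Affymetrix rice array after 5 days at high temperature (37 °C by day, 30 °C by night) or at optimal temperature (30 °C by day, 25 °C by night). Each of the 4 groups held 3 arrays described as biological replicates, 12 in all, so single genes were estimated with limited precision. The deposited signals covered 57381 probe sets, of which 33610 were bright enough to test. Correlation between replicates ran from 0.948 to 0.977. The first principal component held 49.9% of the variance and parted the high-temperature arrays from the optimal ones, and the next held 28.1% and parted the lines at optimal temperature. A probe set was said to rise or fall when its adjusted p was under 0.05 and its log2 change was at least 1 in size. Counts of genes or probe sets higher, lower, positive or negative in a contrast used the same rule and are not counts of signs.

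Control transcripts differed between the groups before any rice gene was considered. The 3′/5′ ratio of the bacterial Dap control, a transcript added to RNA to follow labelling, was 17.5 ± 1.92 (SD, n = 3) in line 252 and 17.9 ± 1.65 in line 082 at high temperature. At optimal temperature it was 2.23 ± 0.11 and 2.12 ± 0.34. The Thr control had ratios of 27.3 ± 3.89 and 29.9 ± 7.68 at high temperature against 3.98 ± 0.414 and 3.13 ± 0.285 at optimal temperature. The shifts were smaller for Phe (4.30 and 4.87 against 1.41 and 1.11) and Lys (2.05 and 1.76 against 1.02 and 0.86). The 18S rRNA signal was 1164 ± 189 in line 252 and 22254 ± 3562 in line 082 at optimal temperature, and 10855 ± 522 and 9128 ± 1930 at high temperature. Median signals of the arrays were 36.5 to 41.9 at high temperature and 55.2 to 68.4 at optimal temperature.

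**Figure D1:**
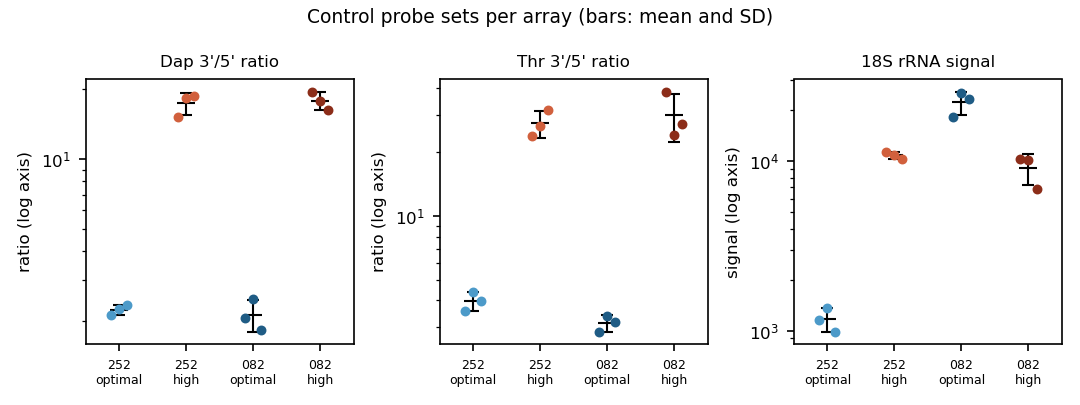
Control probe sets on each array by group: 3′/5′ signal ratio of the Dap and Thr controls (no unit) and 18S rRNA signal (intensity), on log axes, with points for arrays and bars for mean and SD (n = 3). The Dap ratio was 17.5 and 17.9 in the high-temperature groups against 2.23 and 2.12 in the optimal groups.

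In the heat tolerant line 252, dehydrin genes rose at high temperature while genes of DNA replication and mitosis fell. RAB21 (LOC4350454), a dehydrin that accumulates in drying or abscisic acid treated tissue, had a signal of 2514 ± 947 (SD, n = 3) at high temperature and 12.7 ± 11.7 at optimal temperature. Its log2 change was 6.47 ± 0.32 (SE; adjusted p = 3.8e-08), or 5.01 with 64 and 7.83 with 1 added to the signals in place of 16. The mitotic cyclin gene CYCB2-2 (LOC4342121) went the other way, from 3432 ± 639 to 2.29 ± 0.264, a log2 change of −7.54 ± 0.30 (adjusted p = 1.0e-08). As 2.29 lies far under the median signal of the arrays, the size of this fall depended on the added 16, and it was −5.70 with 64 and −10.01 with 1. Clock genes also changed: the morning gene CCA1 (LOC4344703) rose by 4.64 ± 0.32 and the evening gene PCL1 (LOC4326391) fell by 7.13 ± 0.35. In this line 3167 probe sets rose and 6523 fell.

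Other strong rises in line 252 belonged to GER3 (5.84 ± 0.85) and GER2 (4.46 ± 0.70), which encode germin-like cell wall proteins, to the bZIP factor gene TGAL1 (4.81 ± 0.29) and to the glutaredoxin gene GRXC1 (4.41 ± 0.49). The homeodomain-leucine zipper genes HOX12 (4.32 ± 0.26) and HOX24 (4.21 ± 0.43) rose with them. Among the deepest falls were the aquaporin PIP2-7 (−7.30 ± 0.55), the wall-loosening beta-expansin EXPB9 (−6.57 ± 0.45), the aspartic protease AP25 (−6.44 ± 0.77) and the kinesin KIN10A (−5.95 ± 0.40). YSL7 (−5.92 ± 0.43), of a family of metal-chelate transporters, and MET1-2 (−5.91 ± 0.24) fell about as far.

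Small heat shock proteins, which hold unfolding proteins in soluble form, leaned upwards in line 252. Of 18 measured members 9 rose, 1 fell and 8 did not pass (9 and 2 when adjusted over the list alone). HSP18.6 rose by 3.95 ± 0.30, from 164 ± 67.0 to 2709 ± 621, and HSP23.2 (2.81 ± 0.42), HSP17.9A (2.75 ± 0.19) and HSP18.1 (2.49 ± 0.27) also rose. HSP22.3, named after its values were seen, was the member that fell (−1.55). The list had a median of 0.97 and an adjusted p of 0.022, and the adjusted p was 0.38 with an estimated correlation between genes. LEA proteins and dehydrins, protectants of drying cells, were higher in 6 of 7 members, also when adjusted over the list alone, with Emp1 the member that did not pass. RAB16D (3.71 ± 0.45), RAB16B (3.69 ± 0.43) and LEA19 (3.64 ± 0.27) were examples. The median was 3.64 and the adjusted p 0.0027 (adjusted p = 0.38 with an estimated correlation).

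None of the 6 HSP90 and ClpB chaperone genes passed in line 252, where HSP81-2 changed by 0.92 ± 0.10 and the disaggregase CLPB1 by 0.83 ± 0.28. Without replicate 1 of line 252 at high temperature CLPB1 passed (1.14). Of 5 DnaJ co-chaperones DJA6 rose by 2.54 ± 0.22 and DJB6 fell by 1.62 ± 0.22. Among 23 heat stress regulators 3 rose and 6 fell; HSFC2A rose by 3.80 ± 0.29, while HSFA3 (−1.85 ± 0.24) and HSFC1B (−1.72 ± 0.35) fell. Of the HSFA2 class, central to acquired thermotolerance, HSFA2A (−0.90 ± 0.46), HSFA2D (0.67 ± 0.16) and HSFA2E (0.95 ± 0.15) did not pass, though HSFA2E passed without replicate 1 of line 252 at high (1.01) or at optimal temperature (1.03). HSFA2C fell by 1.23 ± 0.38, a call lost without replicate 2 (−1.14) or 3 (−0.82) at high temperature or replicate 3 at optimal temperature (−1.11). In the endoplasmic reticulum folding list 9 of 19 genes fell and 0 rose, with BIP1, an ER chaperone, down from 11315 ± 799 to 3736 ± 1533 (−1.67 ± 0.25), and PDIL2-3 at −2.45 ± 0.27 (list adjusted p = 0.058).

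Histone, DNA replication and mitotic cyclin genes fell together in line 252: 19 of 21 fell, 0 rose and 2 did not pass, and 19 fell when adjusted over the list alone. Besides CYCB2-2, the B-type cyclin CYCB1-1 (−5.88 ± 0.23) and the replicative helicase genes MCM3 (−5.65 ± 0.47) and MCM5 (−5.45 ± 0.61) fell. The list's median was −3.60 and its adjusted p 6.9e-09, and 0.38 with an estimated correlation. Meiosis genes did not pass as a list (adjusted p = 0.19), although 4 of 11 fell, among them CRC1 (−3.21 ± 0.44), SPO11-4 (−2.82 ± 0.38) and MER3 (−2.27 ± 0.35). In the list of pectin enzymes, beta-expansins and pollen-named genes 4 of 11 fell, including EXPB17 (−4.64 ± 0.34), and the list had an adjusted p of 0.12. Of 6 tapetum and pollen wall genes CYP703A3 fell by 1.85 ± 0.40.

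Starch synthesis genes showed 1 rise and 4 falls among 12, led by the sucrose synthase genes SUS3 (−5.0 ± 0.76) and SUS1 (−3.23 ± 0.34). Of 23 sugar transport and invertase genes 6 rose and 5 fell; SWEET2B rose by 3.04 ± 0.37, and the sugar exporter SWEET5 (−5.69 ± 0.37) and the cell wall invertase gene CIN2 (−4.30 ± 0.52) fell. The plastid lipoxygenase gene CM-LOX1 (−5.24 ± 0.72) and its relative CM-LOX2 (−3.24 ± 0.34) fell, within a jasmonate list of 32 with 3 rises and 3 falls. WRKY76 (−4.68 ± 0.28) and WRKY62 (−3.58 ± 0.36), repressors of defence, were among 3 of 7 WRKY and pathogenesis-related genes that fell. Of 26 MADS-box floral regulators 6 rose and 6 fell, from MADS1 (1.88 ± 0.17) to MADS21 (−3.25 ± 0.50) and MADS29 (−3.22 ± 0.59). SODCC.2 (1.82 ± 0.12) and MDAR2 (1.68 ± 0.28) rose and 3 of 22 antioxidant genes fell, including APX5 (−1.76 ± 0.26). PSAG alone rose among 9 photosynthesis genes (2.78 ± 0.33), 2 of 24 ribosomal protein genes fell, and 0 of 7 seed storage genes passed. The class III peroxidases PRX74 (−3.44 ± 0.58) and LOC4344277 (−2.36 ± 0.54) fell out of 3 measured, too few for a list test.

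Beside these falls in line 252, the mean 3′/5′ ratio of Dap was 17.5 at high temperature and 2.23 at optimal temperature, and the signal of GI, a clock gene chosen after PCL1 and CCA1 had been seen but before its own values were read, was 897 and 10277. The split of the calls hung on scaling: 4404 rose and 4593 fell after quantile normalization, 5059 and 4587 after centring on the 75th percentile, and 1610 and 10763 after scaling to the hybridization spikes. Centring on the 75th percentile ended the call of the small heat shock list (adjusted p = 0.057).

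**Figure D2:**
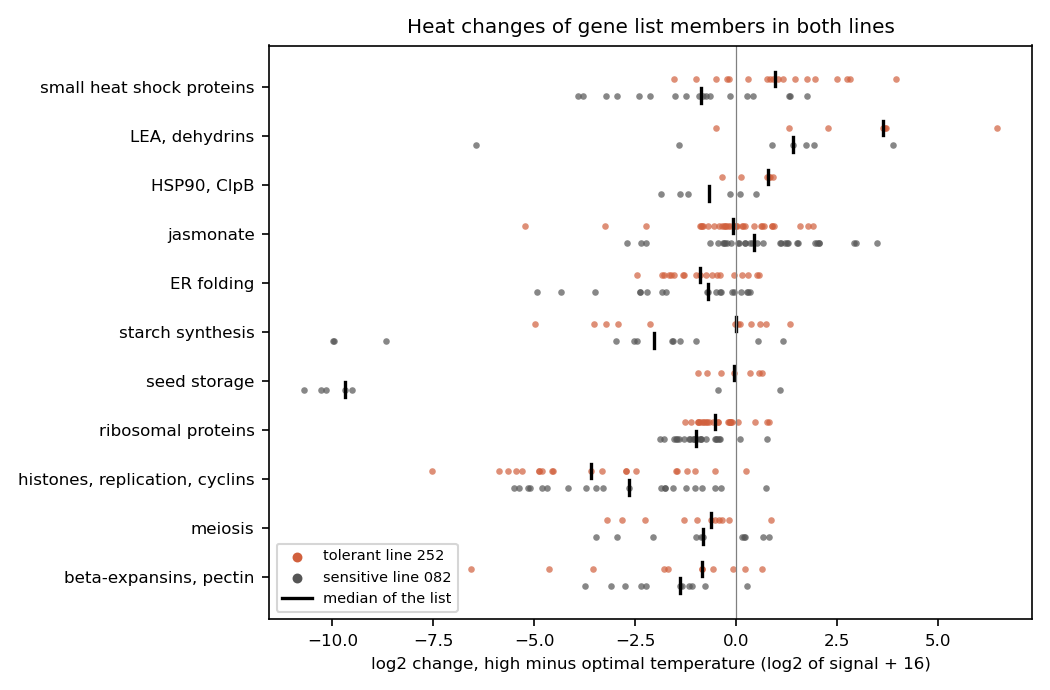
Log2 change from optimal to high temperature of each measured member of 11 gene lists in line 252 (orange) and line 082 (grey), with a black bar for the list's median. Small heat shock proteins had medians of 0.97 and −0.87, and histone, replication and cyclin genes −3.60 and −2.67.

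In the heat sensitive line 082 grain storage and starch genes fell steeply at high temperature, and small heat shock genes fell more often than they rose. GLUA-1 (LOC4327027), which encodes a glutelin stored in endosperm, had a signal of 38422 ± 5913 (SD, n = 3) at optimal temperature and 7.35 ± 6.12 at high temperature, a log2 change of −10.71 ± 0.50 (SE; adjusted p = 1.6e-08). As 7.35 lies far under the median signal of the arrays, the size of this fall depended on the added 16, and it was −9.07 with 64 and −12.56 with 1. GBSS-I, the granule-bound enzyme that makes amylose, fell by 9.99 ± 1.28, from 33936 ± 3256 to 19.5 ± 13.9. Among named genes the strongest rise belonged to HOX12 (5.48 ± 0.26), from 139 ± 18.8 to 6934 ± 1106. In this line 4788 probe sets rose and 7353 fell.

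Genes that rose along with HOX12 in line 082 were GER2 (5.03 ± 0.70), the mannose-binding lectin gene ML (4.65 ± 0.22), SAUR39 (4.22 ± 0.38), a member of an auxin-responsive family, and hox14 (4.17 ± 0.36). OsCASPL1D1 and pinA rose by 4.01 ± 0.35 and 4.01 ± 0.11, and TGAL1 by 3.93 ± 0.29. Of 7 seed storage genes 5 fell and 1 rose (5 and 1 when adjusted over the list alone), with GLUA-3 (−10.29 ± 0.50), GLUD-1 (−10.16 ± 0.27), GLUB-5 (−9.69 ± 0.29) and the prolamin gene PROLM25 (−9.51 ± 0.43) beside GLUA-1. The riser was GLUA-2 by 1.08, named after its values were seen, while another of its probe sets fell by 8.78. The list's median was −9.69 and its adjusted p 6.7e-04 (adjusted p = 0.27 with an estimated correlation). The seed allergen gene RA17 fell by 9.65 ± 0.41.

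Starch synthesis fell as a list in line 082: 9 of 12 genes fell, 1 rose and 2 did not pass, with the same counts over the list alone. SUS3 (−9.96 ± 0.76), SSII-3 (−8.69 ± 1.13) and SUS1 (−2.97 ± 0.34) fell with GBSS-I. The median was −2.03 and the adjusted p 0.0014 (adjusted p = 0.27 with an estimated correlation). Sugar transport and invertase genes were mixed, with 5 rises and 4 falls among 23. SWEET15 (−4.82 ± 0.77), CIN2 (−4.49 ± 0.52) and SWEET11 (−4.31 ± 0.83), the last a sugar exporter that feeds the grain, fell, and the monosaccharide transporter gene MST3 rose by 3.28 ± 0.37.

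Of 18 small heat shock genes in line 082, 8 fell, 3 rose and 7 did not pass, also when adjusted over the list alone. HSP26.7 fell by 3.93 ± 0.42, from 1421 ± 407 to 94.7 ± 85.7, and HSP24.1 (−3.81 ± 0.48), HSP16.9B (−3.22 ± 0.39) and HSP16.9A (−2.95 ± 0.30) fell as well. The list had a median of −0.87 and an adjusted p of 0.040, and 0.43 with an estimated correlation. Its mean log2 signal was 10.24 to 10.45 on the 082 optimal arrays, which also held the bright grain storage genes. On the 9 other arrays it was 8.21 to 9.57. As the stage of the panicles was not given, heat and unequal panicles cannot be told apart for these falls. CLPB-M (−1.87 ± 0.21), CLPB1 (−1.39 ± 0.28) and HSP81-1 (−1.20 ± 0.11) fell among 6 HSP90 and ClpB genes (list adjusted p = 0.27). HSFA2A fell by 3.30 ± 0.46, HSFB2C by 2.47 ± 0.32 and HSFB2B by 2.35 ± 0.44, within 23 heat stress regulators of which 6 fell and 3 rose. HSFA2D (0.44 ± 0.16) and HSFA2C (0.26 ± 0.38) did not pass, and HSFA2E rose by 1.05 ± 0.15, under the minimum of 1 without replicate 1 at high (0.99) or 3 at optimal temperature (0.96). DJA6 rose by 2.29 ± 0.22 and DJB6 fell by 2.38 ± 0.22 among 5 DnaJ co-chaperones.

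Endoplasmic reticulum folding genes fell in line 082, 8 of 19 with 11 not passing, and 8 over the list alone. PDIL1-4 (−4.94 ± 0.27) and PDIL2-3 (−4.34 ± 0.27), which form disulfide bonds, fell deepest, and BIP1 fell by 2.39 ± 0.25. The median was −0.69 and the adjusted p 0.0018 (adjusted p = 0.40 with an estimated correlation). Histone, replication and cyclin genes fell in 17 of 21 cases (17 over the list alone), with MCM3 (−5.50 ± 0.47), CYCB2-2 (−5.37 ± 0.30) and MCM2 (−5.16 ± 0.57). Their median was −2.67 and the adjusted p 3.9e-07 (adjusted p = 0.27 with an estimated correlation). Cytosolic ribosomal protein genes fell in 12 of 24 cases, also over the list alone, for example RPL5 (−1.88 ± 0.20) and rps20 (−1.78 ± 0.14). Their median was −0.99 and the adjusted p 3.3e-06, or 0.44 with an estimated correlation.

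Among pectin enzymes, beta-expansins and pollen-named genes 8 of 11 fell in line 082 (8 over the list alone), including EXPB7 (−3.74 ± 0.75), the pectin methylesterase inhibitor gene PMEI8 (−3.10 ± 0.50) and EXPB9 (−2.77 ± 0.45). The median was −1.40 and the adjusted p 0.017 (adjusted p = 0.44 with an estimated correlation). Of 6 tapetum genes 3 fell, led by EAT1 (−2.29 ± 0.38), a regulator of tapetum cell death, and of 11 meiosis genes SPO11-4 (−3.46 ± 0.38), CRC1 (−2.95 ± 0.44) and MER3 (−2.06 ± 0.35) fell. Photosynthesis genes leaned upwards, with 2 of 9 rising, among them PSAG (1.66 ± 0.33), also over the list alone. Their median was 0.79 and the adjusted p 0.031 (adjusted p = 0.59 with an estimated correlation).

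Jasmonate genes of line 082 rose in 14 of 32 cases and fell in 3, though the list missed the threshold (adjusted p = 0.051). The signalling repressor genes JAZ11 (3.49 ± 0.27) and JAZ5 (2.97 ± 0.30) and the synthesis gene AOS3 (2.91 ± 0.41) rose, and OPR12 fell by 2.72 ± 0.42. Dehydrin and LEA genes split, with 4 of 7 up and 2 down: RAB16D rose by 3.88 ± 0.45 and Emp1, an LEA protein of the embryo, fell by 6.44 ± 0.26. The 1-Cys peroxiredoxin R1C-Prx of seeds fell by 7.53 ± 0.30 and CAT-A rose by 1.58 ± 0.20 among 22 antioxidant genes with 3 rises and 2 falls. Of 26 MADS-box genes 9 rose and 4 fell, from MADS26 (2.94 ± 0.40) to MADS22 (−3.86 ± 0.53) and MADS27 (−3.72 ± 0.39). WRKY76 fell by 2.75 ± 0.28 and WRKY71 rose by 1.63 ± 0.41 among 7, and PRX112 (−2.24 ± 0.25) fell among 3 class III peroxidases.

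Of 4 grain markers chosen before their values were read, 3 fell with the storage genes in line 082. NF-Y4 had 7119 ± 2126 at optimal temperature and 15.0 ± 14.4 at high temperature, VP1 had 1142 ± 582 and 11.99 ± 5.33, CPDK1 changed by −1.74 ± 0.16, and FLO6 did not pass (0.09 ± 0.26; adjusted p = 0.79). The split in line 082 became 6222 up and 5439 down after quantile normalization and 6219 and 6038 after centring on the 75th percentile. Array weights ended the small heat shock call (adjusted p = 0.069), as did leaving out replicate 1 of line 082 at optimal temperature (0.075), and the photosynthesis call was lost without replicate 1 at high temperature (0.052) and with a filter at the 75th percentile (0.067).

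Heat calls shared by the lines were more numerous than unrelated calls would give. TGAL1, HOX12, GER2, DJA6 and RAB16D rose in both lines, and MCM3, MCM5, CYCB2-2, CIN2, SUS3, PDIL2-3 and BIP1 fell in both. In all 1689 probe sets rose in both lines where 451 would be met by independence, 3228 fell in both against 1427, and 352 changed in opposite directions against 1622. The heat changes of all probe sets correlated at r = 0.508 between lines. The Dap control ratio also rose alike in lines 252 and 082 (17.5 and 17.9 at high against 2.23 and 2.12 at optimal temperature). Temperature and labelling can therefore not be told apart for the shared calls. The overlap of 4917 split as 2258 up and 2047 down after quantile normalization, 2763 and 2243 after centring on the 75th percentile, and 943 and 4926 after scaling to the spikes.

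**Figure D3:**
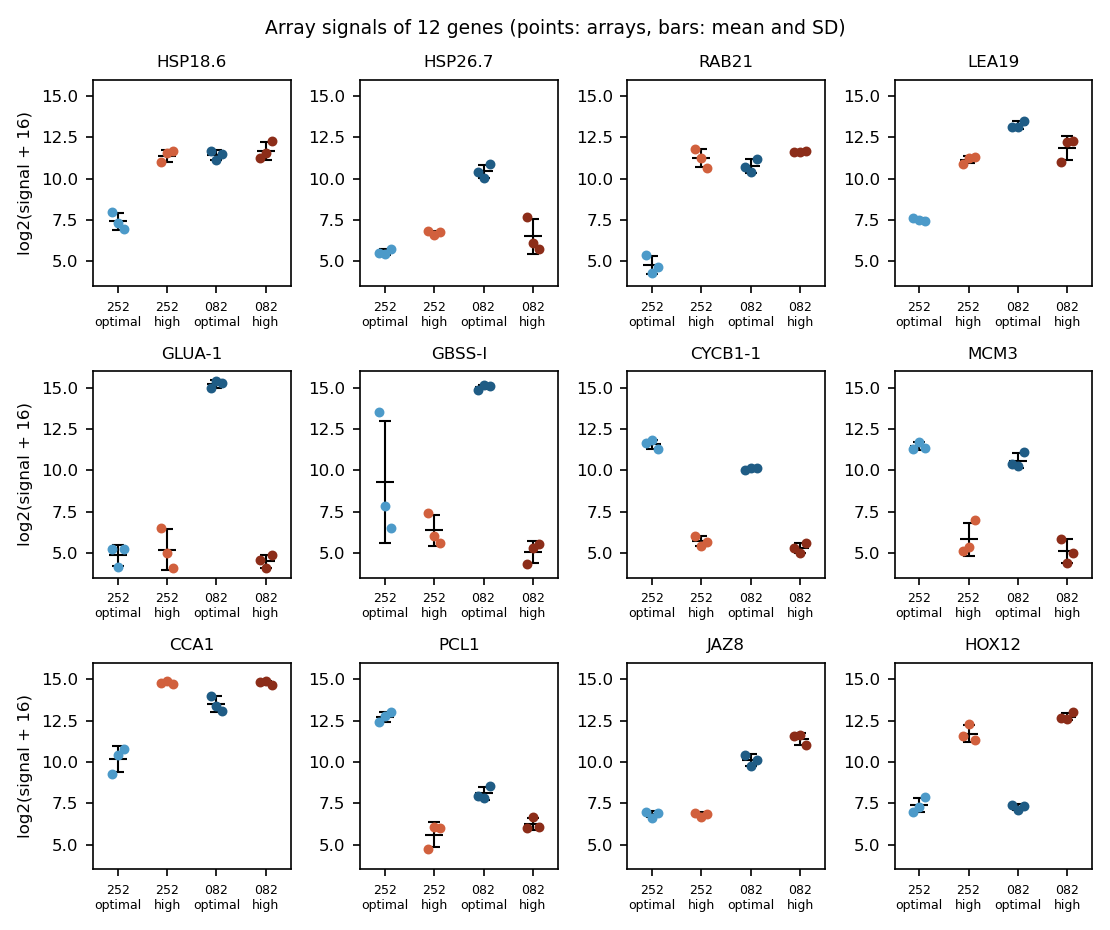
Log2 signal (intensity, 16 added) of 12 genes on each array by line and temperature, with points for arrays and bars for mean and SD (n = 3). HSP26.7, GLUA-1 and LEA19 stood highest in line 082 at optimal temperature, while PCL1 stood highest in line 252 at optimal temperature.

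The heat changes of the lines differed in grain storage, starch, small heat shock and dehydrin genes, among others. The difference, taken as the log2 heat change in line 252 minus that in line 082, was 11.05 ± 0.71 for GLUA-1 (SE; n = 3 per group; adjusted p = 7.8e-07), or 9.27 with 64 and 12.99 with 1 added to the signals. HSP26.7 differed by 5.10 ± 0.59, with signals of 31.7 ± 5.34 and 91.0 ± 8.47 in line 252 at optimal and high temperature and 1421 ± 407 and 94.7 ± 85.7 in line 082. RAB21 differed by 5.58 ± 0.45, and its signal in line 082 was already 1777 ± 534 at optimal temperature. PCL1 differed the other way (−5.28 ± 0.49), with 6896 ± 1336 in line 252 and 265 ± 78.0 in line 082 at optimal temperature. The difference passed as positive for 3700 probe sets and as negative for 4128.

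The difference passed as positive for 11 of 18 small heat shock genes and as negative for 1 (11 and 1 over the list alone). It came in part through falls in line 082, such as HSP26.7 at −3.93 against 1.17 in line 252. Line 252 differed from line 082 by a list median of −2.04 at optimal temperature and 0.07 at high temperature. The difference of heat changes thus came mainly from unequal levels at optimal temperature. HSP24.1 (4.73 ± 0.68), HSP16.9A (4.70 ± 0.43) and HSP16.9B (4.24 ± 0.56) joined HSP26.7. The median was 2.16 and the adjusted p 2.2e-06 (adjusted p = 0.057 with an estimated correlation). HSP90 and ClpB genes had a median of 0.90, with CLPB1 (2.22 ± 0.39) and CLPB-M (1.98 ± 0.30) passing of 6, also over the list alone (adjusted p = 4.5e-04, and 0.14 with an estimated correlation). The regulators HSFB2B (3.23 ± 0.62), HSFB2A (3.22 ± 0.27), HSFB2C (2.94 ± 0.45) and HSFA2A (2.41 ± 0.64) differed in the same direction and HSFC1B (−2.90 ± 0.50) in the other. HSFA2C (−1.50 ± 0.54), HSFA2D (0.22 ± 0.22) and HSFA2E (−0.10 ± 0.21) did not pass, though HSFA2C did without replicate 1 of line 252 (−1.999) or 2 of line 082 (−1.76) at high temperature.

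Dehydrin and LEA genes differed upwards in 4 of 7 cases (4 over the list alone), with Emp1 (5.93 ± 0.37), LEA19 (5.06 ± 0.39) and RAB16B (2.28 ± 0.60) beside RAB21. The median was 2.28 and the adjusted p 0.0014 (adjusted p = 0.18 with an estimated correlation). Seed storage genes differed in 5 of 7 cases (5 over the list alone), including GLUD-1 (10.74 ± 0.39), GLUA-3 (9.91 ± 0.71) and PROLM25 (8.56 ± 0.61). The median was 9.63 and the adjusted p 1.3e-05 (adjusted p = 0.057 with an estimated correlation). Starch genes differed in 8 of 12 cases (8 over the list alone), for example the branching enzyme gene SBE (2.62 ± 0.18) and GBSS-I (7.05 ± 1.81). Replicate 1 of line 252 at optimal temperature stood apart for GBSS-I, at 11646 against 216 and 76.6 in replicates 2 and 3, and without it the difference for GBSS-I was 9.15. The starch list's median was 1.79 and the adjusted p 2.3e-04 (adjusted p = 0.11 with an estimated correlation). The allergen genes RA17 (9.79 ± 0.58), RA14 (9.01 ± 0.86) and RA5 (8.91 ± 0.57) followed the storage genes.

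Jasmonate genes differed downwards, 11 of 32 against 3 upwards (11 and 3 over the list alone), with CM-LOX1 (−5.11 ± 1.02), JAZ5 (−3.52 ± 0.42) and CM-LOX2 (−3.30 ± 0.48). The median was −0.73 and the adjusted p 0.028, or 0.51 with an estimated correlation. Ribosomal protein genes shifted by a median of 0.52, yet RPL3 (1.20 ± 0.26) was the single member of 24 to pass, also over the list alone (adjusted p = 2.2e-04, and 0.51 with an estimated correlation). The kinase gene CIPK10 (−4.71 ± 0.30), the tonoplast aquaporin gene TIP4-1 (−4.57 ± 0.30), the glutamate synthase gene GLT2 (−4.55 ± 0.60) and the potassium transporter gene HAK17 (−4.11 ± 0.41) were among the most negative. DTS2 (−4.26 ± 0.84) and MST3 (−4.20 ± 0.53) stood beside them. Cyclin genes CYCB2-2 (−2.17 ± 0.43) and CYCA2-1 (−1.48 ± 0.39) fell further in line 252, the call of CYCB2-2 being lost with a pseudocount of 1 (adjusted p = 0.075).

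Of 7828 probe sets with a difference, 6362 also differed between lines at optimal temperature with the opposite sign, 306 at high temperature with the same sign and 1202 at neither. These signs are partly built in, because the difference shares 6 arrays with each of the 2 line contrasts (r = −0.904 with the one at optimal temperature). The added bacterial control transcripts differed too, by a median of −1.43 for the difference of heat changes and 1.32 between the lines at optimal temperature. How far these calls follow labelling was not tested. Scaling to the spikes gave 2379 positive and 5901 negative differences, and quantile normalization ended the ribosomal call (adjusted p = 0.12). The jasmonate call was lost with the mean over a gene's probe sets (0.059), scaling to the spikes (0.069), without replicate 3 of line 252 at high temperature (0.059) and without replicate 3 of line 082 at high temperature (0.051).

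At optimal temperature the lines already stood far apart, with grain storage, dehydrin and small heat shock genes lower in line 252. GLUA-1 was 14.9 ± 11.7 in line 252 and 38422 ± 5913 in line 082 (SD, n = 3), a log2 difference of −10.35 ± 0.50 (SE; adjusted p = 2.4e-08), or −8.93 with 64 and −11.79 with 1 added to the signals. LEA19 was 167 ± 10.2 against 9865 ± 1618 (−5.75 ± 0.27) and HSP26.7 31.7 ± 5.34 against 1421 ± 407 (−4.88 ± 0.42). Higher in line 252 were LIR1, a light-regulated gene, at 17706 ± 1431 against 771 ± 295 (4.57 ± 0.27), and PCL1 (4.64 ± 0.35), whereas CCA1 was lower (−3.33 ± 0.32). In line 252, 5142 probe sets were higher and 4066 lower.

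The chlorophyll synthesis gene PORA (4.31 ± 0.32), CM-LOX1 (4.98 ± 0.72), ASP1 (4.80 ± 0.88), GLT2 (4.58 ± 0.43), CIPK10 (4.27 ± 0.21) and AP25 (4.26 ± 0.77) were also higher in line 252. Lower were GLUD-1 (−10.02 ± 0.27), GLUA-3 (−9.48 ± 0.50), RA14 (−9.45 ± 0.61), RA5 (−9.41 ± 0.40), RA17 (−9.08 ± 0.41), PROLM25 (−8.72 ± 0.43) and the seed aquaporin gene TIP3 (−8.69 ± 0.33). Seed storage genes were lower in 5 of 7 cases (5 over the list alone), with a median of −8.72 and an adjusted p of 1.4e-04, or 0.12 with an estimated correlation. Starch genes were lower in 8 of 12 cases (8 over the list alone), such as SBE (−2.52 ± 0.12) and SUS3 (−2.86 ± 0.76). Their median was −1.62 and the adjusted p 3.6e-04 (adjusted p = 0.12 with an estimated correlation).

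Small heat shock, HSP90 and ClpB, and dehydrin lists were lower in line 252 at optimal temperature, as were the grain genes. Other stress lists did not pass: of 23 heat stress regulators 4 were higher and 7 lower (list adjusted p = 0.15). Of 22 antioxidant genes 3 were higher and 2 lower (list adjusted p = 0.81). Small heat shock genes were lower in line 252 for 11 of 18 members and higher for 1 (11 and 1 over the list alone), with HSP24.1 (−4.19 ± 0.48), HSP18.6 (−4.0 ± 0.30) and HSP16.9A (−3.93 ± 0.30). The median was −2.04 and the adjusted p 3.9e-06 (adjusted p = 0.090 with an estimated correlation). CLPB1 (−2.16 ± 0.28) and CLPB-M (−1.66 ± 0.21) were lower among 6 HSP90 and ClpB genes, also over the list alone, whose median was −0.81 (adjusted p = 5.6e-04, and 0.12 with an estimated correlation). HSFB2A (−3.10 ± 0.19), HSFB2C (−2.85 ± 0.32) and HSFA2A (−2.22 ± 0.46) were lower and HSFC1B higher (2.92 ± 0.35), while HSFA2C (0.47 ± 0.38) and HSFA2E (0.21 ± 0.15) did not pass. Dehydrin and LEA genes were lower in 4 of 7 cases (4 over the list alone), with Emp1 (−6.37 ± 0.26), RAB21 (−6.00 ± 0.32) and RAB16B (−3.32 ± 0.43). Their median was −3.32 and the adjusted p 1.4e-04 (adjusted p = 0.12 with an estimated correlation).

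Endoplasmic reticulum folding genes were lower in 5 of 19 cases and higher in 2 at optimal temperature (5 and 2 over the list alone), from PDIL1-4 (−3.97 ± 0.27) to PDIL1-2 (1.85 ± 0.30). The median was −0.67 and the adjusted p 0.022 (adjusted p = 0.41 with an estimated correlation). Histone, replication and cyclin genes were higher in 6 of 21 cases and lower in 1 (6 and 1 over the list alone), for example CYCA2-1 (2.05 ± 0.27), CYCB2-2 (1.82 ± 0.30) and CYCB1-1 (1.48 ± 0.23). Their median was 0.88 and the adjusted p 0.035, or 0.57 with an estimated correlation. Ribosomal protein genes shifted by a median of −0.40 with 0 of 24 passing, also over the list alone, RPL5 at −0.96 ± 0.20 (list adjusted p = 8.0e-05, and 0.50 with an estimated correlation). Without replicate 1 of line 082 at optimal temperature RPL5 (−1.11) and RPL30 (−1.08) passed. RPL30 also passed without replicate 1 of line 252 at optimal temperature (−1.03). Among lists that did not pass, jasmonate genes were higher in 10 of 32 cases and lower in 3, including JAZ8 (−3.25 ± 0.23), MADS-box genes higher in 10 of 26 and lower in 3, and sugar transport genes higher in 9 of 23 and lower in 4. The argonaute gene MEL1 of premeiotic germ cells was higher in line 252 (2.16 ± 0.32) and EAT1 lower (−2.42 ± 0.38).

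The 3 arrays of line 082 at optimal temperature lay above all 9 others, with a mean log2 signal at least 4-fold higher, for 1471 probe sets. They lay below all 9, with a mean at least 4-fold lower, for 427. Without both sets 7415 probe sets differed between the lines. The split became 4078 higher and 5024 lower after centring on the 75th percentile and 7094 and 3072 after scaling to the spikes. Quantile normalization ended the calls of ribosomal (adjusted p = 0.11) and folding genes (0.088), and the histone call was lost with a pseudocount of 1 (0.074), a filter at the 75th percentile (0.051), scaling to the spikes (0.058) and without replicate 1 or 2 of either line at optimal temperature. The call of CYCB2-2 was lost with a pseudocount of 1 (1.84; adjusted p = 0.056).

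At high temperature few genes differed between the lines. The jasmonate repressor gene JAZ8 (LOC4347164) was 97.3 ± 11 in line 252 and 2728 ± 605 in line 082 (SD, n = 3), a log2 difference of −4.58 ± 0.23 (SE; adjusted p = 1.2e-07). MADS26, a MADS-box gene of stress responses, was 136 ± 10.7 against 1304 ± 423 (−3.07 ± 0.40). BC1L9 (LOC4349011), of the COBRA-like cell wall family, was 443 ± 198 against 25.7 ± 11.8 (3.42 ± 0.36). The heme oxygenase gene HO2 was 1476 ± 149 against 350 ± 30.7 (2.03 ± 0.17). Line 252 was higher at 209 probe sets and lower at 382, against 9208 calls between the lines at optimal temperature.

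The replication factor gene RFC4 (1.68 ± 0.17), the floral activator MADS50 (1.43 ± 0.24) and the peptidase gene AARE2 (1.42 ± 0.21) were higher in line 252 at high temperature, as was OsSPO11B (1.18 ± 0.20), of a family that starts meiotic recombination. OrysaZxb (−2.31 ± 0.38), XBOS36 (−1.58 ± 0.24), of a family of ubiquitin ligases, and OsTrx18 (−1.40 ± 0.21) were lower. Of 32 jasmonate genes 3 were lower and 0 higher (4 and 0 over the list alone), the others being JAZ11 (−1.45 ± 0.27) and JAZ12 (−1.16 ± 0.17), which no longer passed without replicate 3 of line 082 at high temperature (−1.25 and −0.96). The median was −0.14 and the adjusted p 0.0065 (adjusted p = 0.72 with an estimated correlation).

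Heat shock genes did not pass at high temperature. With limma 0 of 18 small heat shock genes passed, also when adjusted over the list alone, and CLPB1 (0.06 ± 0.28), HSFA2A (0.18 ± 0.46), HSFA2C (−1.03 ± 0.38), HSFA2D (0.25 ± 0.16) and HSFA2E (0.10 ± 0.15) did not, though HSFA2C (−1.53) and HSP16.9B (1.59) did without replicate 1 of line 252 and HSP17.7 (1.01) without replicate 3 of line 082 at high temperature. Dehydrin and LEA genes shifted by a median of −0.69 with 0 of 7 passing, also over the list alone, such as RAB16B (−1.04 ± 0.43; list adjusted p = 0.0065, and 0.72 with an estimated correlation). Pectin enzymes, beta-expansins and pollen-named genes shifted by 0.49 with 0 of 11 passing, also over the list alone, EXPB7 at 2.25 ± 0.75 (list adjusted p = 0.040, and 0.72 with an estimated correlation). At high temperature RAB16B passed without replicate 1 (−1.61) and EXPB7 without replicate 2 of line 252 (3.14). Seed storage genes shifted by 0.43 with 1 of 7 passing, also over the list alone (adjusted p = 0.040, and 0.72 with an estimated correlation). That gene was GLUB-5 (1.58 ± 0.29) at signals of 95.9 ± 52.2 and 19.8 ± 8.62, and a pseudocount of 64 ended its call. MADS17 (1.35 ± 0.25) also passed but was lost without replicate 3 of line 082 at high temperature.

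With fry, a rotation test in place of camera, 0 lists passed at high temperature, against 4 with camera. Without replicate 3 of line 252 at high temperature the jasmonate (adjusted p = 0.055), dehydrin (0.097) and pectin (0.31) calls were lost.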

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

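The tests of labelling and of a swap of samples for the grain genes, of temperature acting alike on the clock, and of labelling size among heat calls were chosen after the results were seen.

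All but 1 of the values below are differences of heat changes between the lines, tested as an interaction. Such a difference can stem from unequal levels at optimal temperature and does not by itself show a different response to heat. A difference was called for 7828 of 33610 probe sets (23.3%), 7 gene lists (0 with an estimated correlation) and 85 of 148 genes named for the heat and interaction contrasts. The share among named genes is raised by the naming rule, which picked genes by their called changes. List medians of the difference were 2.16 for small heat shock proteins, 0.90 for HSP90 and ClpB, 1.79 for starch synthesis, 0.52 for ribosomal proteins, −0.73 for jasmonate, 2.28 for LEA proteins and dehydrins, and 9.63 for seed storage proteins. The value of another kind was the Dap 3′/5′ ratio, a control outside the main measurement, at 17.7 on average over the 6 high-temperature arrays.

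Among seed and starch genes the differences were GLUA-1 11.05, GLUD-1 10.74, GLUA-3 9.91, GLUB-5 9.63, PROLM25 8.56, RA17 9.79, RA14 9.01, RA5 8.91, GBSS-I 7.05, SSII-3 5.15, SUS3 4.97, SBE 2.62 and R1C-Prx 7.83. Chaperones and folding enzymes had HSP26.7 5.10, HSP24.1 4.73, HSP16.9A 4.70, HSP16.9B 4.24, HSP18.6 3.70, HSP18.1 3.14, HSP17.9A 2.33, CLPB1 2.22, CLPB-M 1.98, DJC27 1.24, PDIL1-4 4.53, PDIL2-3 1.89, PDIL1-2 −2.04 and PDIL2-1 −1.45. Heat stress factors had HSFB2B 3.23, HSFB2A 3.22, HSFB2C 2.94, HSFA2A 2.41, HSFC2A 2.0, HSFA3 −1.01 and HSFC1B −2.90. Dehydrin and LEA genes had Emp1 5.93, RAB21 5.58, LEA19 5.06 and RAB16B 2.28. Germin and regulator genes had GER3 6.48, CCA1 3.36, HOX24 1.97, HOX12 −1.16 and PCL1 −5.28.

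Sugar transport and wall genes had SWEET15 3.56, SWEET2B 2.77, SWEET5 −3.61, MST3 −4.20, PMEI8 3.32, EXPB9 −3.81, EXPB17 −3.31 and EXPB10 −2.45. Jasmonate genes had JAZ2 2.92, OPR12 1.81, JAZ11 −1.59, LOX5 −2.30, CM-LOX2 −3.30, JAZ5 −3.52 and CM-LOX1 −5.11. MADS-box genes had MADS27 3.39, MADS22 2.72, MADS4 −2.07 and MADS26 −2.74, WRKY genes WRKY76 −1.93, WRKY24 −2.54 and WRKY62 −2.62, and the tapetum gene EAT1 2.85. Cell cycle genes had CYCB1-1 −1.07, CYCB2-1 −1.16, CenH3 −1.45, CYCA2-1 −1.48 and CYCB2-2 −2.17. Antioxidant, peroxidase, photosynthesis and ribosomal genes had SODCC.2 1.37, APX8 −1.25, PRX112 1.35, PSAH −1.21 and RPL3 1.20. Others were CIPK10 −4.71, TIP4-1 −4.57, GLT2 −4.55, DTS2 −4.26, HAK17 −4.11, OsCASPL1D1 −3.36, pinA −3.31, YSL7 −2.79 and ML −2.24.

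Of the 85 genes 11 lost the call of this difference when 1 of the 12 arrays at a time was left out. PSAH lost it in 10 cases (adjusted p 0.057 to 0.11), APX8 in 9 (0.053 to 0.093), HSFA3 in 8 (0.053 to 0.092), OPR12 in 8 (0.051 to 0.090) and HOX24 in 8 (0.050 to 0.065). HOX12 lost it in 7 (0.051 to 0.081), SSII-3 in 7 (0.057 to 0.072), CenH3 in 6 (0.052 to 0.079), CYCB1-1 in 4 (0.050 to 0.072), SWEET15 in 4 (0.052 to 0.065) and EXPB10 in 2 (0.050 to 0.054).

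Grain storage genes were bright in the 082 optimal arrays and dim in the others, while the starch gene GBSS-I was also bright in replicate 1 of 252 at optimal temperature (11646). The labelling difference is excluded as the whole cause, since the probe set furthest apart among 79 controls with a signal above 500 between the optimal groups (18S rRNA) differed by 4.78 and the seed storage genes by a median of −8.72. Developing grain in the panicles of that group may be the source: 3 of 4 grain markers were lower in 252 (NF-Y4 −6.40, VP1 −4.10, CPDK1 −2.82), FLO6 (0.74) did not pass, and CPDK1 (3983 to 8375) and FLO6 (691 to 1148) had signals in the other groups too. A swap of 1 or 2 samples would leave bright and dim arrays within a group, whereas 0 of the 9 other arrays had GLUA-1 above a signal of 1000. GLUA-1 belongs to the pattern, so this restates it and is not a separate test. A swap of all 3 with 252 at optimal or 082 at high temperature is excluded by the crossed pairs of groups. Between these, 0 probe sets lay at least 4-fold apart on every array, against 54 between the lines and 266 between the temperatures. A swap of all 3 with 252 at high temperature, which would only trade these 54 and 266, stays open, as do samples from outside the series and an untested difference of the lines in development.

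Clock genes split the arrays: PCL1 and GI were bright in the 252 optimal arrays (6896 and 10277) and CCA1 was dim there (600 to 1758) against 8655 to 16456 in 082 at optimal temperature and means of 28757 and 28275 at high temperature. The heat change of PCL1 differed by −5.28 between lines, but PCL1 is one of the genes that raised the pattern. GI (−3.07 ± 0.20) and PRR1 (−1.99 ± 0.41), chosen before their values were read, differed in the same direction. Temperature acting alike in both lines is thus excluded as the whole cause. A different time of day at sampling is a candidate explanation: GI and PRR1, which peak towards dusk, had a mean heat change of −3.58 in 252. In 082 the changes were −0.43 for GI and −1.68 for PRR1, and of the day genes PRR95 fell in 252 (−1.93) and not in 082 (−0.09), while PRR73 (0.13) and DTH7 (−0.08) did not pass in 252 and rose in 082 (1.16 and 1.62). A response of the clock to heat that differs between the lines was not tested apart from it, because no sampling times were given.

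The heat calls coincide with differences of control probe sets: the Dap ratio ran from 15.2 to 19.6 in the 6 high-temperature arrays, and 93.4% of the heat calls in 252 were smaller than the largest change (3.73) among the 79 control probe sets with a signal above 500 on at least 1 array. That probe set was the 18S rRNA of rice and not a labelling control. The median absolute change of the 79 was 0.64, and the median change of the added bacterial transcripts was −1.17, against 0.13 for heat in 082. Among labelling controls the 5′ signal of Dap fell from 3724 to 373 with heat in 252 and from 1643 to 399 in 082. Labelling differences and the temperature cannot be told apart for those calls, as each group of arrays had a single temperature and the Dap ratio differed with it. The median change of the added bacterial transcripts was 1.32 between the lines at optimal temperature, −0.10 at high temperature and −1.43 for the difference of heat changes. Apart from the grain storage genes, labelling was not tested as a cause of the calls in these contrasts. For heat in 082 the size of labelling differences was not set against the calls, and the largest control change there was 4.92 (5′ actin of rice). The 18S rRNA signal rose with heat in 252 (1164 to 10855) but not in 082 (22254 to 9128).

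Shuffled group memberships were compared with the real ones. For heat in 252 (9690 calls; highest other split 0), heat in 082 (12141; 0), the lines at optimal temperature (9208; 0) and the lines at high temperature (591; 45), the 10 splits of 6 arrays are too few for a share under 0.05, and 1 of the 10 gave as many calls, the real one. The same limit holds for the 8 gene lists in 082 (highest other 7, 1 of 10 splits as many) and the 8 at optimal temperature (6, 1 of 10). For the 3 lists in 252, 7 of 10 splits gave as many (highest other 6). For the 4 lists at high temperature, 5 of 10 did (highest other 7). Mixed arrays thus passed as many lists or more there, so chance cannot be excluded for these 2 results. For the overlap of 4917 (1 of 100 splits as many, highest other 0) the splits decide nothing, since mixed arrays gave 0 heat calls in either line and so no overlap. For the difference of heat changes (7828) 2 of 100 splits gave as many, with a highest other of 8479. In 11 of the drawn splits the real lines stood at optimal temperature with mixed arrays at high temperature, giving 6637 to 8479 calls. The others gave at most 52, which points to a structure carried by the optimal arrays. As the count followed the line labels at optimal temperature, these splits cannot exclude chance for the difference of heat changes. For the 7 lists of this difference 19 of 100 splits gave as many (highest other 9), so chance cannot be excluded.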

How the results depend on the processing

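Scaling to the hybridization spikes and the counts without probe sets that set the 082 optimal arrays apart were chosen after seeing the data. Of the alternatives tried, none turned the direction of a list: over 30 list values that passed, 541 comparisons kept their side of the threshold and 71 lost it. Over 368 gene values 6713 kept their side, 148 lost it, 36 gained it and 12 changed sign, none of which had passed. Signal over background limits dim genes, since median signals were 36.5 to 68.4.

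Counts moved by over 1.5 times as follows, and the cause was not tested unless stated. A filter at the 75th percentile, which tests fewer probe sets, gave 5532 calls for heat in 252, 7211 for heat in 082, 5069 for their difference, 5272 at optimal temperature, 335 at high temperature and an overlap of 3160. With 1 probe set per gene (16542 genes), again fewer tests, these were 5536, 6334, 4217, 4769, 225 and 2974. With no fold minimum, which lets small changes pass, heat in 252 had 15517, heat in 082 18427, optimal temperature 15037 and the overlap 9042. Array weights gave 924 at high temperature. Counts moved by less than this without the probe sets that set the 082 optimal arrays apart, to 9036, 10256, 6203, 7415 and 541, with an overlap of 4409.

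For heat in 252, 3 lists passed, against 5 with quantile normalization, 5 with spike scaling, 6 with a filter at the 75th percentile and 6 with array weights. At high temperature 4 lists passed, against 2 with a pseudocount of 64, 2 with no filter, 2 with a filter at the 75th percentile and 2 with array weights. With an estimated correlation camera passed 0 lists in each of the 5 contrasts, and fry passed 13 for heat in 252, 13 for heat in 082, 12 for their difference, 16 at optimal temperature and 0 at high temperature. The cause was not tested.

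Leaving out 1 array at a time gave 8658 to 9784 calls for heat in 252, 10970 to 13188 for heat in 082, 6730 to 8849 for their difference, 8250 to 10020 at optimal temperature, 424 to 603 at high temperature and an overlap of 4373 to 5112. Lists ran from 3 to 6 for heat in 252, 8 to 9 for heat in 082, 7 to 9 for the difference and at optimal temperature, and 1 to 4 at high temperature, where 1 was without replicate 3 of 252 and 2 without replicate 1 or 2 of 082.

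Relative to the main values, the median change of all probe sets moved by 0.27 for heat in 252 and 0.27 in 082 with quantile normalization. It moved by 0.30, 0.19, 0.11 (difference) and −0.17 (optimal) with centring on the 75th percentile, and by −0.43, −0.13, −0.31 and 0.23 with spike scaling.

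Signs turned for genes that had not passed, and the cause was not tested. With centring on the 75th percentile HSFA2E became 0.00905 for the difference and HSFA2D −0.14 at optimal temperature; with spike scaling HSFA2D became −0.085 for the difference and CLPB1 −0.017 at high temperature. Leaving out arrays, LOC4344277 ran from −0.017 to 0.94, CLPB1 from −0.25 to 0.38 and HSFA2A from −0.089 to 0.68 at high temperature, HSFA2C from −0.0045 to 0.53 for heat in 082 and HSFA2D from −0.12 to 0.23 at optimal temperature.

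Replicate numbers did not pair the arrays: 18 pairs of the same number correlated from −0.20 to 0.13, 2 of them over 0.1, and pairs of different numbers from −0.17 to 0.23. With the replicate number as a block the counts were 9633, 12112, 7680, 9148 and 539, the overlap 4894 and the lists 3, 8, 7, 8 and 3.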

Other observations

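The families below share a name stem and were chosen after the data were seen, as were the genes named with them.

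Genes with the name stem KIN, chiefly kinesins, whose products move along microtubules, mostly fell in both lines at high temperature. The stem was matched by letters alone and took in KIN17 (−0.09 in line 252 and −0.62 in line 082), which may not be a kinesin. In line 252, 20 of 29 fell and 0 rose, among them KIN12C (−5.89 ± 0.44, SE), KIN14E (−5.85 ± 0.26) and KIN5C (−4.57 ± 0.27), with a median of −2.59 and an adjusted p over 47 families of 2.3e-05, or 0.59 with an estimated correlation. In line 082, 18 fell and 2 rose, the latter KIN14M (2.17 ± 0.30) and KIN14K (1.42 ± 0.25), with a median of −1.46 and an adjusted p of 0.0010, or 0.54 with an estimated correlation. Cellulose synthase genes fell in 7 of 9 cases in line 082, with a median of −2.41 and an adjusted p of 0.0053 (adjusted p = 0.54 with an estimated correlation). CESA7 (−4.94 ± 0.37), CESA4 (−4.83 ± 0.36) and CESA9 (−3.63 ± 0.47), which build secondary walls, fell deepest. In line 252, 5 of the 9 fell, by less for CESA7 (−2.23), CESA4 (−1.98) and CESA9 (−1.37). The heat change in 252 minus that in 082 passed as a positive difference for 5 (median 1.16, adjusted p = 0.015, and 0.72 with an estimated correlation). SAP genes, zinc finger proteins of stress responses, rose in 4 of 11 cases in line 252, including SAP2 (2.22 ± 0.20), SAP3 (1.84 ± 0.11) and SAP5 (1.68 ± 0.33). Their median was 0.62 and the adjusted p 0.036 (adjusted p = 0.59 with an estimated correlation).

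Some genes differed between the lines at both temperatures. In line 252, 80 probe sets were higher at optimal and at high temperature where independence would give 32.0, and 175 were lower against 46.2; 42 went in opposite directions against 83.7. Of the 255 with 1 direction, 188 had no called difference of heat changes. JAZ8 was lower in line 252 at optimal (−3.25 ± 0.23) and at high temperature (−4.58 ± 0.23). Its signal was 83.1 to 112 on all arrays of line 252. Whether the probes match both lines equally could not be checked for such genes. Higher were the flowering gene MADS50 (1.55 ± 0.24 and 1.43 ± 0.24), the manganese and cadmium transporter gene NRAMP5 (1.77 ± 0.25 and 1.33 ± 0.25) and the tocopherol synthesis gene G-TMT (1.76 ± 0.19 and 1.07 ± 0.19). The JAZ family was lower in line 252 at high temperature, with 3 of 13 members passing, a median of −0.73 and an adjusted p of 2.7e-04 (adjusted p = 0.77 with an estimated correlation).

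The 3′/5′ ratio of rice actin ran from 67.3 to 105 in line 252 and 72.4 to 279 in line 082 at high temperature, and from 39.4 to 66.8 and 9.51 to 12.1 at optimal temperature. That of rice GAPDH overlapped between the temperatures, at 2.98 to 14.8 and 1.36 to 9.03 against 0.57 to 9.10 and 1.01 to 8.70.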
